A study of Caenorhabditis elegans with 2 samples.

How the data were processed

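Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole *Caenorhabditis elegans* at the L4 larval stage, 48 hours old, from worms synchronised by bleaching and starvation at L1. The worms carried a CRISPR insertion that fuses GFP, a degron, a protease site and 3xFLAG to the dmd-9 gene on chromosome IV, and the fusion protein was precipitated with an anti-GFP antibody. Chromatin was sheared by sonication to a size range of 200 to 800 bp, per the labels. The series holds 1 group of 2 biological replicates, so the comparisons are between replicates, between peak lists, and between peaks and the rest of the genome. No other strain, stage or treatment was compared.

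The deposited peak lists are on ce11, which has the same sequence coordinates as the WBcel235 assembly. The aligner, the peak caller and its settings are not given in the sources used here. Per the labels a control library exists, and each list was derived from the immunoprecipitation and that control. The control and the read alignments were not used here. Read counts were not used here either, so the depth of each replicate is unknown and no interval or limit that needs it is given. Intervals on shares of peaks are exact (Clopper-Pearson) 95% intervals and cover counting error only.

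The authors made 4 ranked lists and 4 thresholded lists, 1 of each from replicate 1, from replicate 2, from both replicates pooled and from the 2 replicates against each other. The larger thresholded list, from the pooled reads, is called the joint list, and the thresholded list from the 2 replicates against each other is called the conservative list. The deposited signal of each peak is the caller's signal value, and it was not scaled between lists: a peak in the pooled list has about the sum of its values in the replicates. The deposited −log10 values are the q value of each peak and, in the ranked lists, the local and global irreproducible discovery rate (IDR). The deposited score is a fixed multiple of the negative log2 of the global IDR, up to 1000. By these values the authors' threshold was a global IDR of 0.01, since every thresholded peak has a global IDR at or under it. Of the columns that hold paired calls in the ranked lists, 14 could not be mapped to a replicate and were not used. The signals of the paired calls in the list from the 2 replicates were used, in a correlation where the order of the pair does not matter.

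Gene positions came from Ensembl annotation release 115. A peak was placed by its summit, in the first of these classes that held it: from 1000 bp upstream to 200 bp downstream of an annotated 5' end of a protein-coding gene (the 5' end window), coding exon, UTR, intron, non-coding gene or pseudogene, and other. Shares of summits in each class, overlap between replicates, and peaks within 100 bp of small RNA genes were set against 1000 circular shifts of the list along each chromosome. These shift tests are two-sided permutation tests. The smallest p they can give is 0.001. Overlap between replicates needed at least 1 shared bp. Peaks per chromosome were set against chromosome length by a two-sided exact binomial test, with Benjamini-Hochberg (BH) adjustment over the 6 nuclear chromosomes. Correlations between replicates and with peak strength are across peaks, which are not independent replicates, and have two-sided permutation p-values from 100000 draws (1000 for the whole ranked list).

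For each of 31 gene lists, the genes with a summit in the 5' end window were compared with all 19978 protein-coding genes (and listed microRNA genes) by a two-sided Fisher's exact test, with BH adjustment over the lists. The lists were written from general knowledge of worm genes or as patterns on gene symbols, and 8 listed symbols had no match in the annotation. For 8 motifs, windows of 50 bp to each side of the summit were compared with windows of the same width centred 400 bp to the left or right of the same summits (two-sided exact McNemar test, BH over motifs). All 2080 6-mers, with reverse complements merged, were compared in the same windows by an exact binomial test on discordant pairs with BH adjustment. A value with an adjusted p at or under 0.05 is called higher or lower. Copies of a sequence elsewhere in the genome were sought with blastn at 90% identity over at least 50% of the sequence.

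The comparisons, tests, gene lists, motifs and the rule for naming genes were chosen before the data were examined. By that rule the named genes are those whose 5' end is nearest to and within 1000 bp of the summits of the 25 peaks of highest signal in the joint list (a pair where 5' ends on both strands lie within that distance), dmd-9 and any DM-domain gene with a peak, and up to 4 members of each gene list with a peak by highest signal, or the first 2 members written where a list had none. Alternatives planned then were the conservative list, each replicate alone and a global IDR of 0.01 for locations, chromosomes, gene lists and motifs, the conservative list and a global IDR of 0.01 for peak counts, each replicate alone for the dmd-9 locus, windows of 500 and 2000 bp, the nearest 5' end only, other backgrounds for genes and chromosomes, permutation of gene labels within 10 bins of upstream length (10000 draws), motif windows of 100 bp, summits below the threshold matched on location class and GC content (Fisher's exact test), 7-mers, and other measures of overlap and correlation. Added after the data were seen were each replicate alone for peak counts, the conservative list, a global IDR of 0.01 and each replicate alone for the 6-mers, the strength gradient and the small RNA genes, and the conservative list and the ranked list from the 2 replicates for the dmd-9 locus. Also added were a global IDR of 0.001, the joint list without peaks of q above 0.05, the joint list without peaks within 100 bp of a tRNA gene, the 5' end of every transcript, gene labels permuted within 10 bins of GC content, the small RNA genes tested apart, and the peaks past the threshold but absent from the thresholded list counted in.

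The tests were checked on simulated data with 1379 peaks. Peaks planted at 20 neuropeptide, 10 homeobox or 5 panneuronal genes gave a call for the planted list and for no other. A DM-domain site planted in 2, 5 or 10 percent of windows was called and in 0 percent was not, while the 6-mers within it were called at 5 percent (1 of them) and 10 percent (2 of them), with 1 other 6-mer called at 10 percent. These sites were planted in windows placed at random. The real summits and flanks differ in GC content (48.9% against 36.04%), so this check does not give the power or the false calls of the motif and 6-mer tests there. Random placement gave no call for gene lists or chromosomes. Each case was simulated 1 time, so these checks give no error rate or power. Background peaks were placed at random over the genome, unlike the joint list with 43.4% of summits in 5' end windows. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, bedtools 2.31.1 and blastn 2.17.0.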

Results

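DMD-9 is a member of the DM-domain family of transcription factors, which is named after doublesex and mab-3. Genomic sites recovered with a tagged DMD-9 protein were mapped by ChIP-seq in whole L4 larvae, in 1 group of 2 biological replicates. Each replicate had its own peak list, and both had joint lists made from them together. The depth of either replicate is unknown.

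The joint list held 1379 peaks, and the replicates agreed on most of their own peaks. Replicate 1 had 569 peaks and replicate 2 had 545, a ratio of 1.04. Of the peaks of replicate 1, 369 (64.9%) overlapped a peak of replicate 2, and 369 (67.7%) of the peaks of replicate 2 overlapped a peak of replicate 1. Shifted placement gave a mean of 1.67 overlapping peaks and at most 7 (permutation p = 0.001, the smallest that 1000 shifts can give). Among the 300 strongest peaks of each replicate, 214 (71.3%) were shared. The joint list contained 550 (96.7%) of the peaks of replicate 1 and 526 (96.5%) of those of replicate 2.

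Peak strength was also related between the replicates. Across 1373 joint peaks with a value in each, Spearman's rho was 0.532 and Pearson's r of log10 signal was 0.630 (two-sided permutation p = 1e-05 for both, the smallest that 100000 draws can give). Below the threshold, across 111035 ranked peaks, rho was 0.255 (permutation p = 0.001, the smallest that 1000 draws can give). The IDR keeps peaks that are alike in rank between parts of the data, so the value in the joint list is not independent of that choice. The peaks of the joint list had a median width of 284 bp and a median signal of 85.4, and they fell into 1286 regions when peaks within 1000 bp were merged. Of the joint peaks, 708 (51.3%) had a q value above 0.05, compared with 33 (5.80%) in replicate 1 and 116 (21.3%) in replicate 2. The conservative list held 1346 peaks, 1089 of which (79.0% of the joint list) were the same peaks, with 290 in the joint list alone and 257 in the conservative list alone. At a global IDR of 0.001 or under, 444 joint peaks were left.

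Peaks were concentrated at the starts of protein-coding genes and were sparse in coding sequence. Of the 1379 summits, 598 (43.4%, 95% interval 40.73 to 46.03) lay in the 5' end window of a protein-coding gene. Shifted placement gave 21.1% ± 1.12 (SD over 1000 shifts), so the share was 2.06-fold higher. Coding exons held 8.19% of summits against 20.02% under shifted placement, introns 24.1% against 31.2%, and UTRs 1.52% against 3.01%. Non-coding genes and pseudogenes held 6.09% against 3.20%, and other sequence 16.8% against 21.5%. Each of these 6 differences had a two-sided permutation p of 0.001, the smallest that the shifts can give. With the peaks past the threshold but absent from the joint list counted in, the share in other sequence was 20.2% (permutation p = 0.258). Ranked peaks below the threshold had 20.7% of their summits at 5' ends, close to shifted placement. In each replicate's own list the share at 5' ends was 52.7% (replicate 1) and 52.8% (replicate 2). The share in coding exons was 1.76% in replicate 1 and 3.12% in replicate 2, and the share in UTRs was 1.05% and 0.917%.

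**Figure D1:**
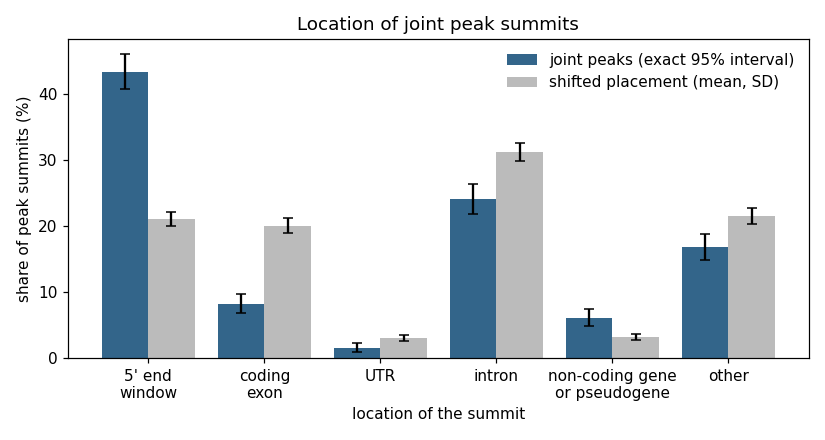
Share of the 1379 joint peak summits (percent) in each class of genomic location, with exact 95% intervals, beside the mean and SD of 1000 circular shifts. The 5' end window held 43.4% of summits against 21.1% under shifted placement, and coding exons 8.19% against 20.02%.

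The 25 strongest peaks of the joint list were present in both replicates' own lists and in the conservative list. Their signals ran from 306 to 750, 17 of them had a protein-coding 5' end within 1000 bp, and 8 had none. Another 6 ranked peaks that passed the threshold but are absent from the joint list were stronger than the 25th. The strongest joint peak lay on chromosome IV at 4727926 to 4728141 (signal 750.2) with no 5' end within that distance, and the next lay on the same chromosome at 4725506 to 4725718 (signal 697), 741 bp downstream of the 5' end of K08F11.1 (WBGene00019541). The third was 252 bp upstream of mog-4 (WBGene00003392, chromosome II, 14561757 to 14561977, signal 683), which encodes a splicing helicase that acts in germline sex determination. The fourth was 642 bp upstream of rpa-2 (WBGene00019767, chromosome I, 4769532 to 4769752, signal 598). Peaks at cnk-1 (chromosome III, signal 521), eel-1 (chromosome IV, signal 499) and rpl-3 (chromosome III, signal 477) were 326, 376 and 285 bp upstream of the 5' ends.

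Among the other peaks of the strongest 25, several had 5' ends on both strands within 1000 bp. The pair F56G4.6 and wbp-4 shared a peak of signal 447, tasp-1 and K01G5.10 a peak of 427, rpl-15 and K11H12.8 a peak of 408, and Y17G9B.5 and rpl-20 a peak of 327, each upstream of both 5' ends. A peak of signal 328 lay 272 bp upstream of C47E8.4 and 839 bp downstream of the 5' end of hsp-90. Single genes were mtcu-2 (signal 387), rpl-35 (signal 375), cox-5A (signal 334) and K12H4.5 (signal 320). A peak of signal 375, 730 bp downstream of the 5' end of ZK1248.17 and 966 bp upstream of H41C03.3, had a summit within 100 bp of an snRNA gene, and the peak of signal 343 at F59C6.18 had a summit within 100 bp of an snoRNA gene. The remaining peaks without a protein-coding gene included chromosome II at 4047959 to 4048165 (signal 579), chromosome V at 14055153 to 14055314 (signal 450) and chromosome IV at 16845527 to 16845669 (signal 364).

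Small RNA genes were tested apart after the locations had been seen, and those for tRNAs carried a large share of the peaks. Genes for tRNAs, which are transcribed by RNA polymerase III, had a joint summit within 100 bp at 221 peaks (16.0%, 95% interval 14.1 to 18.1), 93.2-fold the mean share of 0.172% under shifted placement. Of 612 tRNA genes, 232 (37.9%) had such a peak. Genes for snoRNAs had 52 peaks (3.77%, 31.6-fold) and genes for snRNAs 19 peaks (1.38%, 36.3-fold), at 15.3% and 14.7% of those genes. MicroRNA genes had 6 peaks (0.435%), and piRNA genes had 4 (0.290% against 1.83% under shifted placement, 0.176% in replicate 1 and 0 in replicate 2). All 5 had a two-sided permutation p of 0.001, the smallest the shifts can give, but without replicate 1 the microRNA share of 0.367% had a p of 0.0699. The share near tRNA genes was 20.2% in replicate 1, 17.6% in replicate 2 and 0.242% among ranked peaks below the threshold. For piRNA genes the share among those ranked peaks was 0.780%, also under the 1.83% of shifted placement. The share near snoRNA genes was higher in replicate 1 (6.85%), in replicate 2 (6.24%) and at a global IDR of 0.001 or under (8.11%) than in the joint list, and that near snRNA genes was 2.11% in replicate 1 and 2.20% in replicate 2.

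Repeated tRNA gene sequences had a peak more often than those that occur once, and no isotype passed the test. By isotype the share of genes with a peak ran from 16 of 27 for Asp (59.3%) to 3 of 14 for Phe among the isotypes with more than 1 gene, and none of 22 classes tested by Fisher's exact test differed from the rest (lowest BH-adjusted p = 0.548). On the X chromosome 39.9% of 276 tRNA genes had a peak, and on the autosomes 36.3% of 336 (two-sided Fisher's exact p = 0.403). Genes for tRNA occur in near-identical copies, so which copy a peak belongs to is uncertain from the gene sequence alone. Of 221 joint peaks within 100 bp of a tRNA gene, 13 (5.88%) had a second copy of the peak sequence in the genome. Among joint peaks elsewhere the share was 15.4%. A copy of the tRNA gene alone could be too short to count in that search. A tRNA gene sequence that occurs once in the genome had a peak in 39 of 140 cases (27.9%), and a repeated one in 193 of 472 (40.9%, odds ratio 1.79, two-sided Fisher's exact p = 0.00545).

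**Figure D2:**
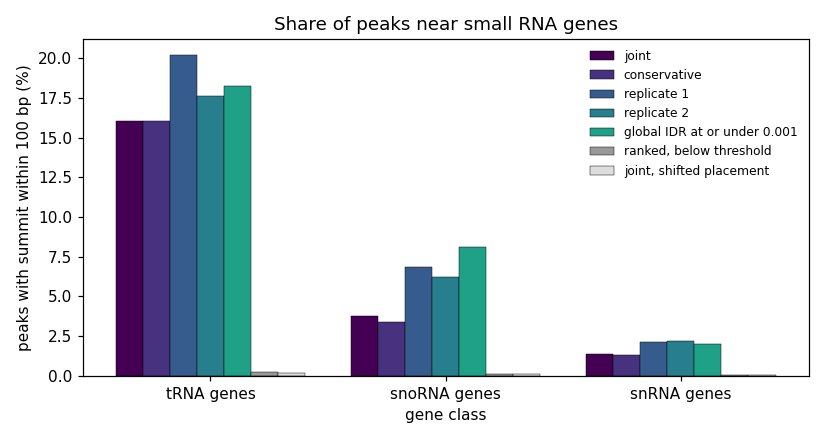
Share of peaks (percent) with a summit within 100 bp of a tRNA, snoRNA or snRNA gene in the joint, conservative and replicate lists, at a global IDR of 0.001 or under, below the threshold and under shifted placement. The tRNA share is 16.0% or more in each thresholded list, against 0.242% below the threshold.

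Genes for the translation machinery, chaperones, oxidative phosphorylation and splicing had more peaks at their 5' ends than other genes. Of 19978 genes, 775 (3.88%) had a joint summit in the 5' end window, and 666 of these were on none of the 31 lists. Ribosomal protein genes had the highest odds, with 29 of 80 (36.3%), an odds ratio of 14.6 (95% interval 8.86 to 23.6) and a BH-adjusted p of 1.76e-19 by two-sided Fisher's exact test. The strongest of their peaks were at rpl-3, rpl-15, rpl-35 and rpl-20, with signals of 477, 408, 375 and 327. Chaperone genes followed with 11 of 59 (odds ratio 5.75, exact test, adjusted p = 0.000147), led by cct-8 (signal 291), dnj-28 (260.0), hsp-60 (223) and hsp-3 (194). Oxidative phosphorylation genes had 7 of 42 (odds ratio 4.99, exact test, adjusted p = 0.00470), with signals of 334 at cox-5A, 172 at atp-1, 132 at cox-6A and 127 at atp-5. Genes for translation factors and tRNA synthetases had 10 of 61 (odds ratio 4.91, exact test, adjusted p = 0.000847), led by iff-2 (signal 224), eif-3.C (163), ears-2 (156) and eif-3.B (147). Splicing genes had 8 of 51 (odds ratio 4.65, exact test, adjusted p = 0.00371), with signals of 275 at prp-19, 150 at snr-4 and 139 at a peak shared by rsp-1 and rsp-2. In each replicate alone the odds ratios were higher than in the joint list: 6.48 in replicate 1 and 8.25 in replicate 2 for oxidative phosphorylation, 5.21 and 7.89 for splicing, 6.25 and 7.499 for translation factor genes, 8.72 and 7.79 for chaperone genes, and 17.8 and 18.3 for ribosomal protein genes. The peaks at snr-4 and cox-6A were within 100 bp of an snRNA gene. Each peak was also given to its nearest 5' end only. The splicing list then had 3 of 51 genes (odds ratio 2.15, exact test, adjusted p = 0.667). Ribosomal protein genes fell to 19 of 80 (odds ratio 10.998) and chaperone genes to 6 of 59 (odds ratio 3.91, exact test, adjusted p = 0.0398). Translation factor genes had 9 of 61 and oxidative phosphorylation genes 6 of 42, both at higher odds ratios than above (6.005 and 5.76). The 598 peaks in 5' end windows gave 775 genes, so genes can share a peak, while the exact test treats genes as independent.

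Chemoreceptor and innate immunity genes had fewer peaks than other genes. Chemoreceptor genes had 8 of 1300 (0.615%, odds ratio 0.145, Fisher's exact test, adjusted p = 5.22e-13), among them sri-5, srh-89, srh-269 and srx-28, with signals of 139 to 84.0, and the peak at srh-269 was within 100 bp of a tRNA gene. In replicate 1 alone 2 chemoreceptor genes had a peak, an odds ratio of 0.0687. Innate immunity genes had 2 of 319 (clec-126 and spp-26, odds ratio 0.154, Fisher's exact test, adjusted p = 0.00371). The peaks at clec-126 and spp-26 were both within 100 bp of a tRNA gene. The innate immunity list was no longer past the threshold of the exact test without replicate 1 (odds ratio 0.151, adjusted p = 0.0930), without replicate 2 (odds ratio 0.296, adjusted p = 0.278) or at a global IDR of 0.001 (odds ratio 0.172, adjusted p = 0.191). The same held without peaks of q above 0.05 (odds ratio 0.245, adjusted p = 0.121 by exact test) and with the nearest 5' end only (odds ratio 0.213, adjusted p = 0.0510).

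**Figure D3:**
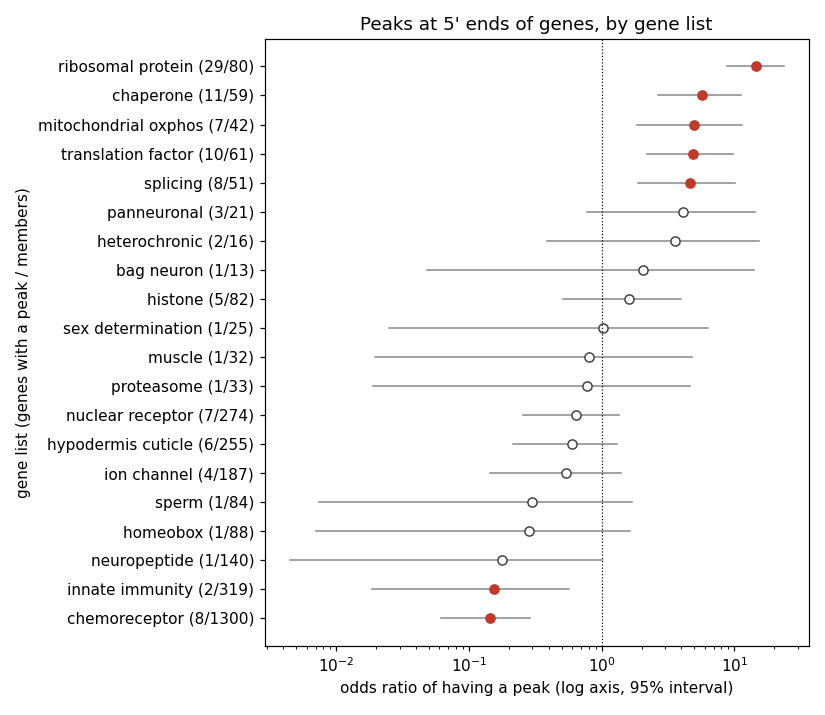
Odds ratio (log axis, 95% interval) of having a joint peak at the 5' end for the gene lists with at least 1 such gene, with the genes with a peak and the members in brackets. Filled points are the 7 lists with a BH-adjusted p at or under 0.05, ribosomal protein genes at the highest odds ratio (14.6) and chemoreceptor genes at the lowest (0.145).

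No excess of peaks was called at genes of sexual differentiation, neurons and other tissues, but many of these lists were too small to exclude one. None of the 10 DM-domain genes tested had a peak (mab-3 and mab-23 among them), nor did any of 10 dosage compensation genes (dpy-21, dpy-26) or 6 vitellogenin genes (vit-1, vit-2). Of 25 sex determination genes, mog-4 was the 1 with a peak. There were 0 peaks at 19 neurotransmitter genes (eat-4, unc-17), 31 sensory neuron genes (odr-1, odr-3), 31 axon guidance genes (unc-6, unc-40), 38 basic helix-loop-helix genes (hlh-1, hlh-10) and 27 gonad and vulva genes (lin-3, let-23). There were also 0 at 15 glial genes (mir-228, ptr-10), 24 intestine genes (elt-2, elt-7) and 31 germline genes (pgl-1, pgl-3). For the lists with 0, gene labels permuted within bins of upstream length gave on average 0.214 (DM-domain) to 1.38 (germline) genes with a peak. The upper limits of their odds ratios ran from 2.53 (basic helix-loop-helix) to 21.1 (vitellogenin), so an excess is not excluded. The chromatin came from whole larvae, and binding confined to few cells was not tested. Of 13 genes of the BAG sensory neurons, gcy-33 had a peak (signal 114), whose summit was within 100 bp of a tRNA gene. Panneuronal genes had 3 of 21 (ehs-1, tbb-1 and syd-2, odds ratio 4.14), of which 0 were in either replicate's own list, at a global IDR of 0.001 or among peaks of q at or under 0.05, and neuropeptide genes 1 of 140 (ins-39, odds ratio 0.177, with 0 genes in replicate 1 alone and an odds ratio of 0.350 in replicate 2 alone). Their Fisher's exact p-values were 0.0460 and 0.0463, and the BH-adjusted value was 0.160 for both.

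The remaining lists had few peaks and no call. Heterochronic genes had 2 of 16 (lin-46 and lin-28), histone genes 5 of 82 (his-37, htz-1, his-24 and his-5 the strongest), and nuclear receptor genes 7 of 274 (nhr-255, nhr-142, nhr-47 and nhr-35 the strongest). Ion channel genes had 4 of 187 (twk-10 and lgc-25, both with the summit within 100 bp of a tRNA gene, lgc-22 and twk-32), and hypodermis and cuticle genes 6 of 255 (col-71, grl-26, col-95 and col-63 the strongest). In replicate 2 alone no hypodermis or cuticle gene had a peak, which passed the threshold as lower (adjusted p = 0.0492 by exact test). Homeobox genes had 1 of 88 (ceh-43, within 100 bp of a tRNA gene), muscle genes 1 of 32 (act-4), sperm genes 1 of 84 (spe-39) and proteasome genes 1 of 33 (rpn-3). The peaks at nhr-255 and grl-26 were also within 100 bp of a tRNA gene. In either replicate alone no ion channel, muscle or sperm gene had a peak. Nuclear receptor genes had 2 in replicate 1 alone and 1 in replicate 2 alone, and proteasome genes had 1 in each. For the lists with few members the intervals were wide, and for DM-domain genes the upper 95% limit of the odds ratio was 11.1.

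Peaks were spread unevenly over the chromosomes. Chromosome III held 259 peaks (18.8%, against 13.7% by length, BH-adjusted p = 1.12e-06 by two-sided exact binomial test), chromosome I 17.7% (against 15.03%, adjusted p = 0.00996) and the X chromosome 280 peaks (20.3%, against 17.7%, adjusted p = 0.0146). Chromosome V held 15.6% (against 20.9%, exact test, adjusted p = 2.26e-06), chromosome IV 14.1% (against 17.4%, adjusted p = 0.00217) and chromosome II 13.5% (against 15.2%, adjusted p = 0.0721). The X chromosome carries 45.1% of the tRNA genes. Among the 1158 peaks over 100 bp from a tRNA gene, the X share was 15.03% (95% interval 13.0 to 17.2), lower than its share of length (exact binomial test, adjusted p = 0.0224). The share of chromosome III in those peaks was 20.03%. The X share did not pass the exact test in either replicate's own list, where it was 20.9% in replicate 1 (adjusted p = 0.0715) and 19.1% in replicate 2 (adjusted p = 0.482). Chromosome I did not pass in the conservative list (16.8%, adjusted p = 0.0876 by exact binomial test), in either replicate alone, at a global IDR of 0.001 or without peaks of q above 0.05. Chromosome IV did not pass in replicate 1 alone (14.2%, adjusted p = 0.0715 by exact binomial test) or at a global IDR of 0.001 (adjusted p = 0.180). Against the share of ranked peaks in place of length, chromosomes I and IV did not pass (adjusted p = 0.149 and 0.428 by exact binomial test) and chromosome II did, as lower (0.0247). Chromosome II also passed as lower against the share of protein-coding 5' ends (exact binomial test, adjusted p = 0.000234) and with the absent peaks counted in (0.0480). At a global IDR of 0.001 chromosome III, at 17.6%, did not pass either (adjusted p = 0.0683 by exact binomial test).

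Summits were rich in GC and in promoter sequences, and no excess of the DM-domain sites over flanks was called. The windows around summits had a mean GC content of 48.9%, against 36.04% in the flanks. The core site of vertebrate DM-domain proteins, ACAWTGT, was in 21 summit windows (1.52%) and in 1.45% of flanks, a ratio of 1.05 (95% interval 0.571 to 1.94, BH-adjusted p = 1 by two-sided exact McNemar test). In the conservative list the ratio was 0.385 (exact test, adjusted p = 0.0129), and in replicate 1 alone it was 0.286 (adjusted p = 0.0412), both lower at summits. These comparisons with flanks do not hold GC content fixed, and the flank sides were drawn anew in each list. The change from the joint list can therefore not be assigned to the peaks alone. Against summits below the threshold matched on location class and GC content, the ratio for ACAWTGT was 1.91 (Fisher's exact test, adjusted p = 0.173). The core of the MAB-3 site, ATGTTGC, was in 0.435% of summit windows and 0.798% of flanks (ratio 0.545, exact test, adjusted p = 0.380). It was in few windows, and its ratio was 0.4 in replicate 1 alone and 6 in replicate 2 alone, neither past the threshold. Against the matched summits its ratio was 0.353 (Fisher's exact test, adjusted p = 0.0679).

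Other motifs, of promoters and E-box factors, were more frequent at summits than in flanks, and GATA and splice acceptor sites were less frequent. A GC box (CCGCCC) was in 6.02% of summit windows and 1.09% of flanks (exact McNemar test, adjusted p = 6.86e-13), a GA repeat (GAGAGAG) in 6.96% and 1.89% (adjusted p = 1.48e-10), the GCGTCTC promoter motif in 5.87% and 1.45% (adjusted p = 3.28e-10), and an E-box (CACGTG) in 3.41% and 1.52% (adjusted p = 0.00248). The GATA site TGATAA was in 3.99% and 8.63% (exact test, adjusted p = 1.01e-06), and the splice acceptor TTTCAG in 8.12% and 19.9% (adjusted p = 6.95e-18). Against summits below the threshold with the same location class and GC content, the GA repeat (6.96% against 3.92%, adjusted p = 0.00215) and GCGTCTC (5.87% against 2.76%, adjusted p = 0.000565, Fisher's exact test) stayed more frequent. In that comparison the GC box was at a ratio of 0.912 (exact test, adjusted p = 0.667), the E-box at 1.38 (0.234), the GATA site at 0.917 (0.703) and the splice acceptor at 0.752 (0.0508). The E-box was also not called by the exact McNemar test in replicate 1 alone (ratio 1.64, adjusted p = 0.303), in replicate 2 alone (ratio 1.17, adjusted p = 0.845), at a global IDR of 0.001 (ratio 2, adjusted p = 0.252) or without peaks of q above 0.05 (ratio 2, adjusted p = 0.0943). The GC box stayed called in replicate 2 alone, at a ratio of 3.18.

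**Figure D4:**
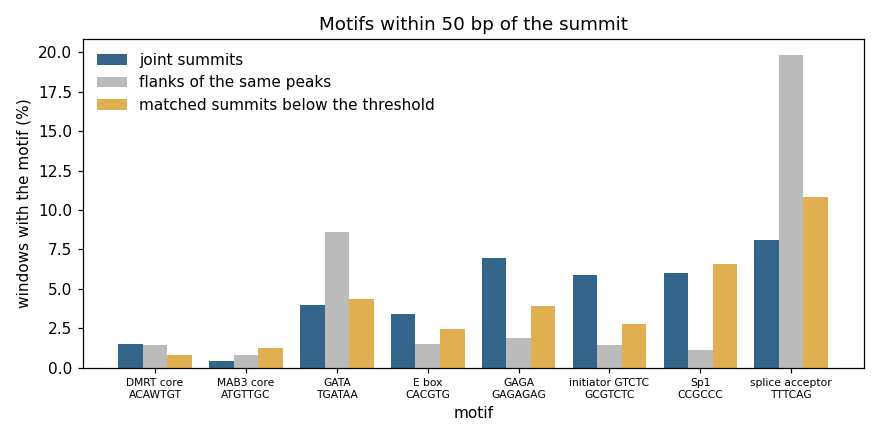
Percent of windows of 50 bp to each side with each of 8 motifs, for joint summits, flanks of the same peaks and summits below the threshold matched on location class and GC content. The GA repeat (6.96%) and GCGTCTC (5.87%) are more frequent at joint summits than in both comparison sets.

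Of 2080 6-mers, 636 were more frequent at summits and 421 less frequent. Both counts were smaller in each replicate alone, where there were fewer peaks. In the joint list the more frequent 6-mers had a median of 4 G or C bases and the less frequent 1. The 6-mer most different among the more frequent was ACGCGC, in 10.4% of summit windows and 1.09% of flanks, followed by CGGCCA (10.8% and 1.38%) and CGAGAG (12.4% and 2.76%). GTTCGA was in 43.9% of the peaks near tRNA genes and 6.22% of other peaks, and GAACCC in 33.5% and 3.71%.

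Strong peaks lay at 5' ends more often than weak ones. In 4 equal groups of the joint list, from the strongest peaks to the weakest, 59.4%, 45.2%, 35.1% and 33.7% of summits were in a 5' end window (rho with signal 0.193, two-sided permutation p = 1e-05, the smallest that the draws can give). The share in coding exons went from 1.16% in the strongest group to 18.6% in the weakest (rho -0.229, the same p). Near tRNA genes the shares were 16.5%, 23.8%, 15.4% and 8.43% (rho 0.0915, permutation p = 0.00056). The DM-domain core ACAWTGT was in 0.290%, 1.74%, 0.870% and 3.20% of the 4 groups (rho -0.0755, permutation p = 0.00457), on 21 windows in all. The MAB-3 core showed no relation (rho 0.00482, permutation p = 0.861).

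The dmd-9 gene itself had no called peak. No thresholded list held a peak in dmd-9 (WBGene00022060, chromosome IV, 3253261 to 3254543) or within 5000 bp of it. In the pooled ranked list there were 19 ranked peaks in that region, the strongest of them at rank 2451 of 112594 with a signal of 59.99 and a global IDR of 0.0481, 1640 bp upstream of the 5' end. The strongest ranked peak of the region in replicate 1 had its summit at 3256224, upstream of the gene, with a global IDR of 0.426. In replicate 2 the strongest was another one, with its summit at 3252819, downstream of the gene, and a global IDR of 0.607.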

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

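The share of joint peaks at tRNA and ribosomal protein genes, the tests at small RNA genes and the permutation within GC content were chosen after the result was seen.

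A set of strong peaks stood outside the list that the comparisons used. In the pooled ranked list 1444 peaks passed a global IDR of 0.01, and 65 of them (4.50%) are absent from the joint list. Their median signal was 97.7, against 85.4 in the joint list, and the strongest, on the X chromosome at 15810941 to 15811171, had a signal of 2547.04. None of the 65 had a summit in a 5' end window or near a tRNA gene, and 6 were stronger than the 25th joint peak. The lists of replicate 1, replicate 2 and the conservative list lack 42, 33 and 61 such peaks.

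Repeated sequence was weighed first for these 65 peaks. A second copy in the genome was found for 61 of them (93.8%, 95% interval 85.0 to 98.3), against 13.9% of joint peaks (odds ratio 94.9, two-sided Fisher's exact p = 2.79e-44). This is consistent with removal by the authors of regions of repeated sequence, and the deposited descriptions name a further file behind the thresholded lists that the ranked lists do not name. What that file holds is not given in the sources used here. No biological explanation was tested, since the design has 1 group.

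The peaks at tRNA genes and at ribosomal protein genes were weighed together. Sharing of reads between exact copies is argued against as the whole cause of the tRNA peaks: tRNA genes whose sequence occurs once had a peak in 27.9% of cases (95% interval 20.6 to 36.1), against 0.366% under shifted placement. Repeated sequences had one more often (odds ratio 1.79, two-sided Fisher's exact p = 0.00545). None of the 9 tRNA genes without a similar place elsewhere had a peak (upper limit 33.6%). Sharing between similar copies may therefore add to the pattern. Taken whole, 13 of 221 joint peaks near tRNA genes (5.88%) had a second copy in the genome, against 15.4% of joint peaks elsewhere. A copy of the tRNA gene alone could be too short to count there, so these shares do not decide. At ribosomal protein genes, permuting gene labels within 10 bins of upstream length left 6.76 times the number of genes with a peak that the draws gave on average, and within 10 bins of GC content 6.52 times, which argues against either as the whole cause. Signal at strongly transcribed genes in any immunoprecipitation cannot be told apart from binding of DMD-9 for these 18.1% of joint peaks, because no untagged or unrelated immunoprecipitation was used here. The same lack limits the other joint peaks, among them those at snoRNA and snRNA genes and at the other gene lists with more peaks.

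The peaks found in the joint or the conservative list alone were weighed against closeness to the threshold. Of 547 such peaks, 386 (70.6%) had a global IDR between 0.01 and 0.05 in the other ranked list, 153 were over 0.05 and 8 were absent from it. The limits, 80% or more for closeness as the cause and under 50% against it, were chosen beforehand and not derived from data. The share lies between them, so the test does not decide. No biological explanation was tested.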

How the results depend on the processing

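Every alternative for the small RNA genes, those for the 6-mers other than 7-mers, those for the strength gradient other than the mean signal of the replicates, leaving out a replicate for peak counts, and the conservative list and the ranked list from the 2 replicates for dmd-9 were chosen after the data were seen. So were the global IDR of 0.001, the removal of peaks with q above 0.05, the removal of peaks near tRNA genes, the 5' end of every transcript, the permutation within GC content and the counting of absent peaks. A tested value was labelled the same if it kept its direction and side of the threshold, or if neither value passed, whatever the direction. Reversed means a changed direction where either value passed. A count moved if it changed by more than a set factor, and the IDR at dmd-9 if it crossed 0.01. Of 785 values recomputed under an alternative, those that answer a comparison were the same in 113 cases, moved in 19, no longer passed in 4 and reversed in 3. Of the others, 616 were the same, 25 no longer passed, 4 came to pass and 1 reversed. The planned global IDR of 0.01 equals the authors' threshold and changed nothing. Its cases are counted among the same, though their outcome was fixed in advance. Gene lists with 0 genes could also not gain one where peaks were only removed. Overlap and correlation between replicates could not be recomputed without a replicate.

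The share of peaks at 5' ends, the share near tRNA genes and the strength gradient held under every alternative tried for them. So did the 5 gene lists with more peaks (4 with the nearest 5' end only). No alternative gave a called peak at dmd-9 either, but none used a looser threshold. A global IDR of 0.001 leaves a subset of the joint list, so it could not add one. The strongest ranked peak near dmd-9 had a global IDR of 0.0481 in the pooled ranked list. The share at 5' ends ran from 35.1% (500 bp window) to 56.8% (global IDR of 0.001).

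Leaving out a replicate in turn gave 545 to 569 peaks, 2 to 3 chromosomes past the threshold in place of 5, an X share of 19.1 to 20.9%, 1 to 2 lists lower, 343 to 370 6-mers higher and 256 to 283 lower, and a ratio of 0.286 to 0.636 for ACAWTGT. A global IDR of 0.001 gave 444 peaks, 1 chromosome, an X share of 20.5% that no longer passed, 1 list lower, 382 6-mers higher and 279 lower. Without peaks of q above 0.05 there were 671 peaks, 3 chromosomes, an X share of 20.3% that no longer passed and 1 list lower. These settings use fewer peaks, which lowers counts of peaks by construction, and for the rest the cause was not tested. With the nearest 5' end only, 1 list was lower, and the cause was not tested. Without peaks near tRNA genes the X share reversed to 15.03%. Against matched summits below the threshold, 2 motifs were higher and 0 lower, and the GC box reversed to 0.912. That setting changes the comparison set, its location class and its GC content together, and the cause was not tested. In the conservative list the ratio for ACAWTGT reversed to 0.385. The flank sides were drawn anew there as well, and the cause was not tested. The unknown depth limits what can be said of regions without a peak.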

Other observations

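The removal of peaks near tRNA genes and the test of the share of windows with the exact core ACAWTGT were chosen after the data were seen.

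A hypothesis was that tRNA genes on the X chromosome account for its higher share of peaks. Among peaks over 100 bp from a tRNA gene the X share was 15.03% (95% interval 13.0 to 17.2), below its share of length (17.7%). The test had foreseen an interval that includes the share of length or lies above it, and the interval lay wholly below it. Neither foreseen outcome was met, so the test does not decide. The X chromosome carries 45.1% of the tRNA genes, so removing peaks near them can lower the X share whatever the cause of the excess. Without those peaks no excess on X was left, and the lower share among the other peaks is unexplained.

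A further hypothesis was that the joint peaks as a set are bound through a DM-domain site. The exact core ACAWTGT was in 1.52% of summit windows (upper 95% limit 2.32%), which argues against binding of most joint peaks through that exact core. In the 4 equal groups from strongest to weakest, the core was in 0.290%, 1.74%, 0.870% and 3.20% of windows (rho -0.0755, permutation p = 0.00457). These shares rest on 21 windows and did not fall evenly with strength, and base composition was not held fixed. The ratio of summits to flanks was 1.05 with an upper 95% limit of 1.94, so an excess at a small share of peaks could exist that these peaks do not resolve, and sites that differ from the core stay open. The ratio was lower than 1 in the conservative list (0.385) and in replicate 1 alone (0.286), with flank sides drawn anew in each list. Against matched summits below the threshold it was 1.91 (adjusted p = 0.173 by Fisher's exact test). The exact site bound by DMD-9 was not known beforehand, and other sites were sought only as the MAB-3 core, 6-mers and 7-mers.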
